A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

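RNA from a Saccharomyces cerevisiae strain of the BY4741 background that lacks SLT2, the MAP kinase of the cell wall integrity pathway, was compared on 4 arrays with 2 channels each. Per the labels, a culture grown in rich medium at 24 °C was divided, Congo red, a dye that binds chitin and disturbs the cell wall, was added to one part at 30 µg/ml, and both parts were collected at 4 h. Every array held treated and untreated RNA. On arrays 1 and 3 the treated RNA was in channel 2, and on arrays 2 and 4 it was in channel 1. Numbers name the arrays as the labels do. Whether the 4 arrays came from separate cultures or from repeated hybridisation of the same RNA is not given in the sources used here, so the p-values measure only the spread between these arrays, which may be technical. All 4 arrays formed 1 group and no array was left out.

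The deposited values are log2 ratios of the channels, one per spot, for 12800 spots. How the authors scanned, filtered or normalized the arrays, which dye each channel carried and which channel is the numerator are not given in the sources used here. On the linear scale 100% of the deposited log2 values were ratios with 3 decimals, within rounding of the deposited figures. A single top value, 16.61 on the log2 scale, equals the log2 of 100000 and stood apart from all others. It was taken as a placeholder for a ratio without a finite value and set to missing (68, 31, 33 and 47 spots on arrays 1 to 4), which left 10759, 11640, 11223 and 11175 spots. Signal over background and spot brightness were not analysed here, and for arrays their number limits the precision.

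The deposited log2 values had medians of 0.43, -0.25, 0.30 and 0.64 on arrays 1 to 4, so no centring by the authors was visible. A rule set before the data were examined called for centring where a median lay over 0.1 from 0, and each array's median was therefore subtracted. A second such rule settled orientation. Across spots, arrays of opposite channel order correlated below 0 (r from -0.38 to -0.19) and arrays of the same order above 0 (r = 0.27 and 0.31), so the values were taken as unturned and arrays 2 and 4 were multiplied by -1. Turning sets the arrays to a common sign, and the p-values and null draws ignore that it was chosen from the same values. That a positive value means more treated than untreated RNA is likely only: it assumes that channel 2 is the numerator, with the labels naming the untreated channel of array 1 as the control. If channel 1 is the numerator, every sign below is the opposite, all together. If the values had been deposited as treated over untreated on every array, the turned means would measure channel order and not treatment. The rule takes this case as less likely but does not exclude it.

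The platform annotation gave 11138 spots 1 gene symbol, none several, and left 1662 spots unnamed here. They belong to 5539 genes, of which 5534 had their symbols updated through the reference gene table (assembly R64). The array's own build is not given in the sources used here, and no coordinates are printed. Spots of one gene were averaged, and the main analysis used the 4481 genes with a value on all 4 arrays. The log2 ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), with Benjamini-Hochberg adjustment and a threshold of 0.05. The effect of channel order was tested in the same model with a second coefficient.

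After the data were examined, a second analysis was added because the paired spots of a gene often disagreed. Adjacent spots of a gene lay within 1 log2 unit in 81.1%, 91.9%, 91.5% and 86.8% of pairs on arrays 1 to 4. It was chosen to name genes after the counts of calls of a first form of it, of centring runs of 400 spots and of both together had been seen beside the 0 calls of the planned analysis (472, 214 and 615 calls in the final scripts), so its p-values do not allow for that choice. This duplicate-spot analysis kept a gene's value on an array only where at least 2 of its spots were measured and their range was at most 1 log2 unit, and it tested the 2804 genes with such values on all 4 arrays in the same way. The filter uses the spread between spots on one array, not between arrays.

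Of 32 gene lists fixed before the data were examined from textbook knowledge, 30 had at least 5 measured genes and were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera also rests its p-values on the few residual degrees of freedom of 4 arrays, and 0 of the 30 lists passed in either analysis. The meiosis list's estimate of 0.0125 was near the preset 0.01, yet its p from camera went from 0.0058 to 0.072. A call lost that way therefore need not come from correlation between genes. Where an alternative left missing values, camera's test on ranked gene statistics (cameraPR) replaced it. The lists cover cell wall synthesis and integrity, stress responses, translation, metabolism, nutrient regulons, the cell cycle, mating, and markers of cells that should be absent (the other mating type and sporulating diploids). Genes were named by a rule fixed at the same time: the 12 highest and 12 lowest mean ratios among genes past the threshold with the same sign on 4 arrays, or, where under 10 passed in a direction, the 10 with the largest moderated t, said not to have passed. For each list of at least 5 genes up to 4 members with the largest mean ratio and the same sign on 4 arrays are eligible, with all members of smaller lists and the 5 loci deleted or disrupted in the strain. The rule was applied to both analyses. Gene length is the span in the reference table. Of the protein-coding spans, 96.3% are multiples of 3, so the span is mostly coding length, and the introns of many ribosomal protein genes make their spans too long.

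The scripts were tested on simulated data with the spread of the real genes and 200 changed genes. With the main analysis (4481 genes) 32% of 2-fold and 79% of 4-fold changes were recovered, and with the duplicate-spot analysis (2804 genes) 87% and 100%. Neither made a call with the wrong sign, and each made 10 false calls. A ribosomal protein list shifted by 0.5 was called in both. In 20 draws in which the spots' own residuals were given random signs, the main analysis made a median of 0 and at most 1 false call, and the duplicate-spot analysis a median of 0 and at most 2. Signs were drawn separately for each gene and array, and the simulated genes were independent. Errors shared between genes, such as those of runs of spots, were thus left out, and the counts of false calls do not cover them.

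Alternatives fixed beforehand varied centring, scaling, quantile normalization, missing values, averaging of spots, a filter on genes ranging over 2 log2 units, the channel-order term, orientation, the pairing of arrays as dye swaps, the variance model and the threshold, and left out each array in turn. Alternatives added after the data were examined kept the placeholder, required agreeing spots, subtracted the median of each run of 400 consecutive spot numbers (how these map to the slide is not given in the sources used here), or removed a loess trend (span 0.5) on log2 gene length from each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.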

Results

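The data are 4 arrays with 2 channels, each comparing RNA of slt2-deleted yeast after 4 h in 30 µg/ml Congo red with RNA of untreated cells of the same strain. The comparison asks which transcripts respond to cell wall stress when the terminal kinase of the cell wall integrity pathway is missing. Arrays 1 and 3 carried the treated RNA in channel 2, arrays 2 and 4 in channel 1. Between 84.1% and 90.9% of the 12800 spots on an array gave a usable ratio. Values below are mean log2 ratios of treated over untreated RNA ± SD over the 4 arrays (n = 4) after centring each array. The direction is likely only, from the labels' use of the untreated channel as the control. If the deposited ratios run the other way, every sign reverses together. Were they instead deposited as treated over untreated on every array, the turned means would measure channel order and not treatment. The sources used here do not exclude that case.

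Transcripts of LRG1, a GTPase-activating protein of the Rho1 switch in cell wall signalling, of PMA2, a plasma membrane proton pump, and of PIR3, a cell wall protein, rose with Congo red in the duplicate-spot analysis, which was chosen after its calls and those of other candidate analyses had been seen. LRG1 stood at 1.49 ± 0.14 (2.80-fold, adjusted p = 0.00483, limma), PMA2 at 1.39 ± 0.18 and PIR3 at 1.23 ± 0.48. SEC12, which starts the coating of vesicles leaving the endoplasmic reticulum, fell to -1.65 ± 0.30 (0.319-fold, adjusted p = 0.00483), and so did the thioredoxin gene TRX1 (-1.21 ± 0.35) and TOM6, part of the import pore of the mitochondrial outer membrane (-1.28 ± 0.32). In that analysis 472 of 2804 genes passed limma's test, 149 higher and 323 lower, each with the same sign on 4 of 4 arrays. That balance depends on the processing: arrays were centred over all spots before the filter. With a trend with gene length removed, 133 passed higher and 86 lower. The planned analysis of 4481 genes called 0 genes at an adjusted p under 0.05. Its smallest adjusted p was 0.0522, and 537 genes lay under 0.1. There 1234 genes had an unadjusted p under 0.05, where chance gives 224, and 41.7% of genes had the same sign on 4 arrays. The orientation was chosen from the agreement of these arrays, so chance values that ignore the choice are too low.

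Among the other genes with the largest rises in the duplicate-spot analysis were ERR3 (1.41 ± 0.47) and ERR2 (1.32 ± 1.05), related to enolase. Their near-identical copy ERR1 stood at -0.90 ± 0.09 in the planned analysis. ERR1 did not meet the spot filter of the duplicate-spot analysis and was not tested there. The largest rises also included PHO81 (1.15 ± 0.20), an inhibitor in the phosphate starvation pathway, and PRO1 (1.10 ± 0.56), the first enzyme of proline synthesis. Others were CKI1 (1.16 ± 0.18), choline kinase, LAG1 (1.05 ± 0.61), a ceramide synthase subunit, and PRM6 (1.56 ± 1.35), a pheromone-regulated membrane protein. YER189W and YAR066W, reading frames named by locus, stood at 1.18 ± 0.23 and 1.36 ± 0.89. PRM6 ranged from 0.012 on array 2 to 3.17 on array 1, so its size is poorly fixed. The other genes with the largest falls were MSR1 (-2.01 ± 1.45), a mitochondrial arginyl-tRNA synthetase, SIR1 (-1.96 ± 1.04), a silencing protein, PIH1 (-1.70 ± 0.73), RPS30A (-1.69 ± 0.98), a ribosomal protein, SPO13 (-1.42 ± 0.89), a regulator of meiosis, YGK3 (-1.28 ± 0.27), a kinase of the GSK-3 family, ROF1 (-1.26 ± 0.17), RSC9 (-1.24 ± 0.64), a subunit of the RSC chromatin remodeller, and TEP1 (-1.21 ± 0.21). The genes of this paragraph except ERR1 had adjusted p between 0.00667 and 0.0451 (limma). For PMA2, PIR3, TRX1 and TOM6 above, it lay between 0.00483 and 0.0111.

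**Figure D1:**
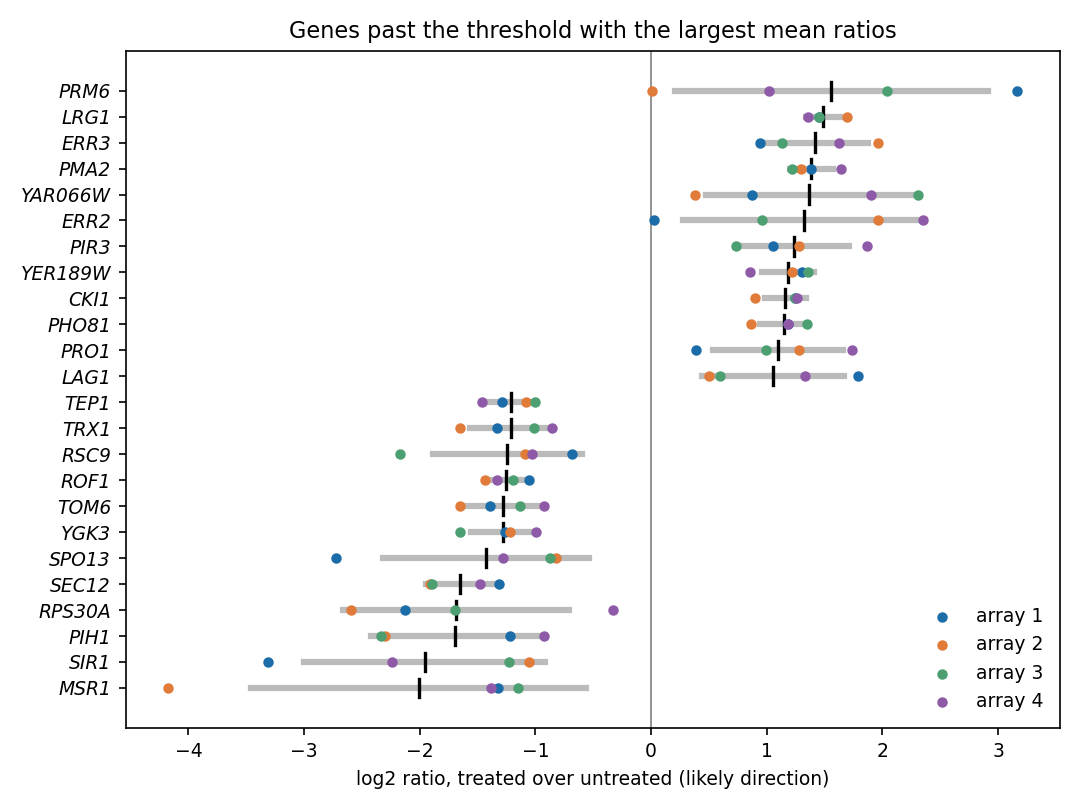
Log2 ratio of treated over untreated RNA (x axis, direction likely only) of the 24 genes with the largest mean ratios among those past the threshold in the duplicate-spot analysis; dots are the 4 arrays, black ticks the means and grey bars 1 SD to either side. LRG1 and PMA2 lie close together on all 4 arrays, while PRM6 is spread over all 4 arrays and MSR1 is spread by array 2.

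In the planned analysis no gene passed. The 10 genes with the largest moderated t above 0, none past the threshold, included TGL2 (2.21 ± 0.40), a lipase, SKN7 (1.97 ± 0.47), a transcription factor of the stress and cell wall response, MSI1 (1.62 ± 0.26), MSF1 (1.34 ± 0.10), AAD3 (1.36 ± 0.26), YVC1 (1.21 ± 0.17), a vacuolar cation channel, MED1 (1.14 ± 0.15) and GDS1 (1.08 ± 0.05), beside LRG1 and PMA2. The 10 with the largest t below 0 included GAT3 (-3.13 ± 0.53), PEP7 (-2.38 ± 0.43), RKM2 (-2.10 ± 0.42), HOF1 (-2.07 ± 0.25), a cytokinesis protein, CBK1 (-2.06 ± 0.29), a kinase of cell separation, AIM17 (-1.83 ± 0.30), YIR042C (-1.69 ± 0.23), PRP19 (-1.60 ± 0.28) and ECM7 (-1.55 ± 0.22), beside SEC12. Their adjusted p lay between 0.0522 and 0.0534.

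The count of 472 calls moved when an array was left out. The same test called 336 of 3542 genes without array 1 and 215 of 2861 without array 2. It called 0 of 2872 without array 3 and 0 of 3019 without array 4. Genes with an unadjusted p under 0.05 (limma) numbered 1132, 808, 724 and 904 in that order. More such genes were found without array 4 than without array 2, so the 0 calls do not show a particular dependence on array 4. With the values as deposited, uncentred, 59 genes passed, 37 higher and 22 lower, and after a trend with gene length was removed 219 passed, 133 higher and 86 lower, 188 of them among the 472. Of 52 called genes followed through the alternatives, 31 still passed without the length trend and 21 did not: PRM6, ERR2, SPO13, CIS3, SKT5, CHS1, FIT2, MFA1, MFA2, RPS22A, ATP15, ATP16, COX9, COX13, HSP10, HYR1, TRX2, HHF1, HHF2, HHT1 and HTA1. For PRM6 (1.56 to 1.61), ERR2 (1.32 to 1.33), SPO13 (-1.42 to -1.31), SKT5 (0.70 to 0.64) and CHS1 (0.66 to 0.59) the mean hardly moved, so removal of the trend ended the call but not the difference. Most of the others shrank, such as MFA1 (-1.07 to -0.36) and COX9 (-0.72 to -0.13). TOM6 and TRX1, spanning 186 and 312 bp, still passed but shrank to -0.69 and -0.77.

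Genes for ribosomal proteins and core histones stood lower with Congo red. The 131 measured ribosomal protein genes had a median of -0.50 (adjusted p = 4.39e-21, camera). With an estimated correlation camera gave an adjusted p of 0.43, so that call was lost, as was every other list's call. Medians of the ribosomal protein genes on arrays 1 to 4 were -0.50, -0.49, -0.49 and -0.49. Of these genes 101 were lower on 4 of 4 arrays and 3 higher. In the planned analysis none passed over all genes, while adjusted over the list alone 71 passed lower and 1 higher. In the duplicate-spot analysis 66 of 130 fell and none rose over all genes, and adjusted over the list alone 90 were lower and 1 higher (RPL7B, named after its value was seen). RPL14A (-1.13 ± 0.36), RPS22A (-1.10 ± 0.48) and RPS31 (-1.08 ± 0.39) fell in that analysis. Fry gave the list an adjusted p of 0.0152.

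All 8 core histone genes were lower on 4 of 4 arrays, with a median of -0.53 (adjusted p = 0.00074, camera). The call was lost with an estimated correlation, 0.71 between these genes (adjusted p = 0.92), and with fry (0.076). In the duplicate-spot analysis 6 fell over all genes, and all 8 adjusted over the list alone. In the planned analysis 7 were lower adjusted over the list alone. HHF2 and HHF1, both encoding histone H4, stood at -0.77 ± 0.24 and -0.66 ± 0.22, HHT1 (histone H3) at -0.59 ± 0.29 and HTA1 (histone H2A) at -0.55 ± 0.28. The call was also lost after the gene length trend was removed (median -0.25, adjusted p = 0.055).

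Ratios moved with gene length, and the ribosomal protein and histone genes are short. In the duplicate-spot analysis the rank correlation of mean ratio with length across genes was 0.37, and 0.33 without ribosomal protein genes. Over the 4476 genes with a length in the planned analysis it was 0.23 and 0.20, and from 0.12 to 0.26 on single arrays. Genes are not independent replicates, so no p is given. Medians ran from -0.53 for 58 genes up to 300 bp to 0.10 for 334 genes between 2400 and 3600 bp, and 218 genes over 3600 bp had a median of 0.0089, so the longest genes did not continue the trend. Up to 1200 bp ribosomal protein genes lay below other genes of the same span, for example at -0.70 against -0.36 between 300 and 450 bp (12 and 198 genes). Between 1200 and 1800 bp 3 ribosomal protein genes had a median of 0.33 against 0.04. After the trend was removed from the planned analysis their median was -0.39 (adjusted p = 4.9e-16, camera), and from the duplicate-spot analysis -0.30 (adjusted p = 4.75e-13). These are values with the preset correlation, and before removal of the trend the call was lost with an estimated correlation (adjusted p = 0.43 and 0.52 in the planned and duplicate-spot analyses). Introns make the spans of many ribosomal protein genes too long, which sets them beside longer genes with higher ratios. This tends to overstate how far they lie below other genes of the same span and after removal of the trend.

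**Figure D2:**
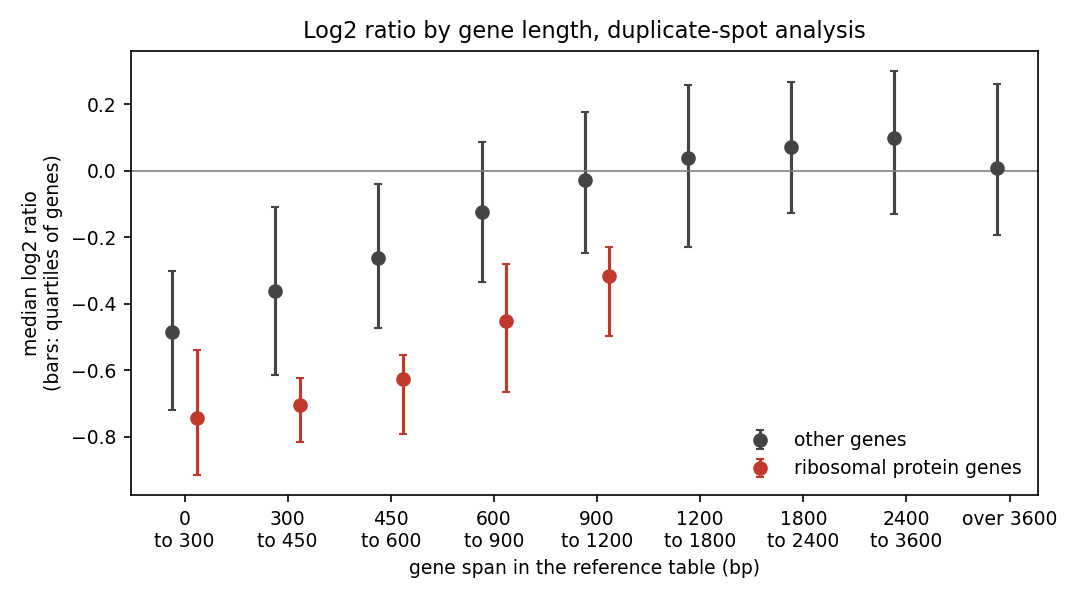
Median log2 ratio of treated over untreated RNA (y axis, direction likely only) against gene span in base pairs (x axis, bins with at least 5 genes) in the duplicate-spot analysis, for ribosomal protein genes (red) and other genes (dark grey); bars are quartiles of genes. Other genes go from -0.48 in the shortest bin to 0.10 between 2400 and 3600 bp and 0.0089 above, and ribosomal protein genes lie lower in each bin shown.

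Respiration and meiosis lists also passed in the planned analysis. Genes of mitochondrial respiration had a median of -0.27 over 38 genes (adjusted p = 0.0145, camera; adjusted p = 0.92 with an estimated correlation and 0.076 by fry; 17 lower and 5 higher on 4 of 4 arrays), with 1 lower adjusted over the list alone, ATP15. In the duplicate-spot analysis 10 of 30 fell, among them ATP15 (-0.94 ± 0.11) and ATP16 (-0.56 ± 0.25) of the ATP synthase and COX9 (-0.72 ± 0.19) and COX13 (-0.69 ± 0.21) of cytochrome c oxidase. The list's own test in the duplicate-spot analysis gave an adjusted p of 0.0975, and 0.95 with an estimated correlation. In the planned analysis the call was also lost without array 3 (median -0.20, adjusted p = 0.061) and with values as deposited (adjusted p = 0.10). Removal of the length trend left a median of -0.05 (adjusted p = 0.78) in the planned analysis and 0.039 (adjusted p = 0.94) in the duplicate-spot analysis. Genes of meiosis and sporulation, programmes of diploid cells, had a median of -0.71 over 13 genes (adjusted p = 0.0436; adjusted p = 0.75 with an estimated correlation and 0.076 by fry), with 4 lower adjusted over the list alone: SPS4 (-2.03 ± 1.00), SPS100 (-2.04 ± 1.17), SPO13 and RED1 (-0.61 ± 0.22). That call was lost without array 1 (median -0.59, adjusted p = 0.14, camera) and without array 4 (-0.67, adjusted p = 0.14). It was lost too with genes on at least 3 arrays (16 genes, median -0.66, adjusted p = 0.060). These settings ended the call but moved the median little. The call was also lost in the duplicate-spot analysis (6 genes, median -0.52, adjusted p = 0.62) and with runs of 400 spots centred (median -0.36, adjusted p = 0.47). SPO13 and RED1 fell in the duplicate-spot analysis.

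The lists for the cell wall did not pass. The 27 measured genes of the cell wall integrity response, targets of the Slt2-activated factor Rlm1, had a median of 0.0044 (adjusted p = 0.89, camera), with 3 higher and 4 lower on 4 of 4 arrays. Over all genes in the duplicate-spot analysis, 1 of 18 rose (PIR3) and 1 fell, CIS3 (-0.72 ± 0.33), which encodes a mannoprotein of the wall. The same counts held adjusted over the list alone. HSP150 (0.29 ± 0.15) and CCW14 (-0.28 ± 0.25) did not pass. DFG5 (-1.87 ± 0.86) and BAG7 (0.77 ± 0.85), measured only in the planned analysis, did not pass over all genes, and DFG5 and PIR3 passed adjusted over the list alone.

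Glucan and chitin genes had a median of -0.07 over 27 genes (adjusted p = 0.89). In the duplicate-spot analysis CHS1, a chitin synthase, rose to 0.66 ± 0.47 and SKT5, an activator of chitin synthase III, to 0.70 ± 0.53, with adjusted p of 0.0464 and 0.048, and none of 20 passed adjusted over the list alone. After the length trend was removed their means were 0.59 and 0.64, little changed, and neither passed (adjusted p = 0.083 and 0.085). Wall mannoproteins had a median of -0.07 over 24 genes (adjusted p = 0.17), and 4 of 18 fell in the duplicate-spot analysis, over all genes and adjusted over the list alone: CWP2 (-1.10 ± 0.22), CCW12 (-0.97 ± 0.11), FIT2 (-0.78 ± 0.28) and FLO9 (-0.69 ± 0.37). Without the length trend CWP2 stood at -0.62, CCW12 at -0.60 and FLO9 at -0.75, which still passed, and FIT2 at -0.46, which did not (adjusted p = 0.10). Components of the Pkc1 pathway had a median of 0.13 over 18 genes (adjusted p = 0.17). LRG1 rose in the duplicate-spot analysis, 1 of 13 genes. SKN7, SLG1 (0.81 ± 0.42), a wall stress sensor, and RHO2 (0.50 ± 0.36) did not pass over all genes, and LRG1 and SKN7 passed adjusted over the list alone in the planned analysis.

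**Figure D3:**
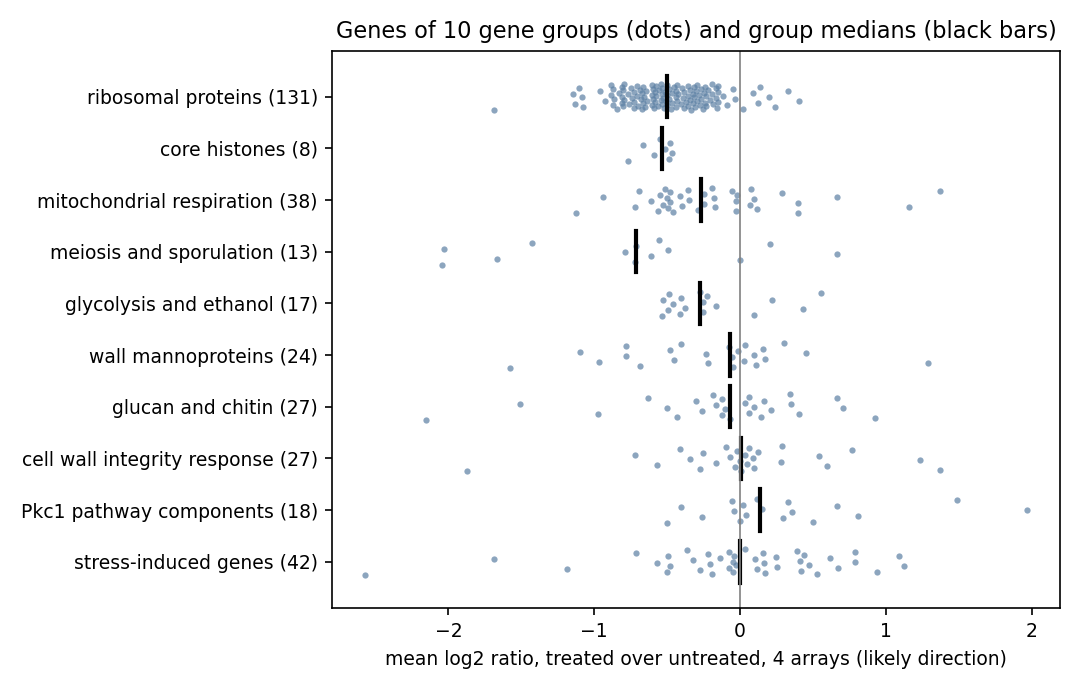
Mean log2 ratio of treated over untreated RNA over 4 arrays (x axis, direction likely only) of each measured gene in 10 gene groups of the planned analysis; dots are genes, black bars group medians, and the number of genes stands in parentheses. Ribosomal proteins (median -0.50) and core histones (-0.53) lie left of 0, and the cell wall integrity response (0.0044) is centred on 0.

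Stress lists fixed beforehand did not pass either. The 42 genes induced in the environmental stress response had a median of 0.0021 (adjusted p = 0.89, camera), and in the duplicate-spot analysis 1 of 27 rose, HSP104, and 1 fell, HOR7, with none adjusted over the list alone. Genes of the oxidative stress response had a median of -0.04 over 25 genes (adjusted p = 0.80), and in the duplicate-spot analysis of -0.17 over 16 (adjusted p = 0.41, and 0.95 with an estimated correlation). Of these 16, 7 fell and 1 rose, OYE3. TSA1 (-0.95 ± 0.31) and AHP1 (-0.82 ± 0.10), both peroxiredoxins, HYR1 (-0.97 ± 0.40), a glutathione peroxidase, and TRX2 (-0.86 ± 0.13), a thioredoxin, were among those that fell. After removal of the length trend TSA1 (-0.71) and AHP1 (-0.54) still passed, and HYR1 (-0.67) and TRX2 (-0.42) did not (adjusted p = 0.055 and 0.072, limma). Each of them shrank, and HYR1 kept a larger difference than AHP1, which passed. Of 16 chaperone genes 1 rose, YDJ1 (1.01 ± 0.36), an Hsp40, and 2 fell, HSP10 (-0.84 ± 0.08) and SSC1 (-0.59 ± 0.24), both mitochondrial. The list as a whole had a median of -0.10 over 19 genes (adjusted p = 0.89). Mating genes had a median of -0.09 over 24 genes (adjusted p = 0.87), and PRM6 rose while MFA2 (-1.10 ± 0.39) and MFA1 (-1.07 ± 0.92), the a-factor genes, fell. The short a-factor genes did not pass after the length trend was removed (adjusted p = 0.17 and 0.49).

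Spots for transcripts that the strain should lack were checked array by array. SLT2 itself is deleted in both channels per the labels, and whether its spots carry signal was not tested. They gave 1.48, -1.29, -1.51 and -1.14 on arrays 1 to 4 (mean -0.62 ± 1.41), and the spots on array 1 disagreed, at 3.66 and -0.70. LEU2 and MET17, also deleted in the background, stood at 0.14 ± 0.17 and 0.10 ± 0.17, and HIS3 at 0.59 ± 1.07 with 2.11 on array 1. URA3 was measured on 2 arrays, at 3.21 and -1.94. STE3 and SAG1, genes of the other mating type, stood at -1.71 ± 0.69 and -1.58 ± 0.97, lower on 4 of 4 arrays. Both passed adjusted over that list of 2 alone, and neither passed over all genes. MF(ALPHA)1, measured on 3 arrays, had a mean of -1.09 ± 0.72 (n = 3), and MF(ALPHA)2, measured on 2, gave -1.82 and -0.32. The meiosis genes above are also not expected to be transcribed in a haploid strain in rich medium. STE3, SAG1 and SPO13 were lower on 4 of 4 arrays all the same, and SPO13 passed in the duplicate-spot analysis. Sign agreement between arrays therefore need not reflect a change in a gene's own transcript.

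The arrays differed in precision. Across the 4481 genes the 6 pairs of turned arrays correlated with a mean r of 0.32 ± 0.08 (from 0.23 to 0.43), and in the duplicate-spot analysis of 2804 genes with a mean of 0.48 ± 0.07 (from 0.37 to 0.56). These correlations are across genes, which are not independent replicates. For channel order limma called 0 of 4481 genes, as for treatment, with 182 at an unadjusted p under 0.05, and 1 of 2804 in the duplicate-spot analysis, with 187. Without array 3, 600 of 4645 genes had an unadjusted p under 0.05 for channel order (smallest adjusted p 0.17). The median size of the channel-order effect was 0.16 log2 units against 0.33 for treatment. The orientation rule turned the arrays so that they agree, and the agreeing part is read as treatment. The smaller channel-order effect follows at least partly from that choice and does not show that channel effects are small. Medians of runs of 400 spots varied from -1.33 to 0.41 on array 2 and from -0.20 to 0.28 on array 4.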

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

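The tests of a channel effect on length, of spot position, of length alone, of a pull toward equal channels and of RNA integrity were chosen after the pattern was seen, as was the duplicate-spot analysis that several of them use. The tests of single arrays and of sign patterns were set down before their results were seen, the latter also for the duplicate-spot analysis, whose count of calls was then known.

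Of 112 results compared across the 4 arrays, 7 had 1 array far from the other 3, where chance gives about 5%. The count is near that share, so these results do not mark any array as faulty. For SLT2 the gap to the nearest array was 0.878 of the whole range, with array 1 apart (1.48 against -1.51 to -1.14). RIP1, a subunit of respiratory complex III, had array 1 apart at 3.51 (0.897 of the range), and SRX1, sulfiredoxin, had it apart at -0.24 (0.898). Array 2 was apart for MSR1 at -4.18 (0.923), CKI1 at 0.90 (0.943), RPS22A at -1.82 (0.838) and RPS31 at -1.66 (0.850). Array 1 had the lowest share of agreeing spot pairs and array 2 the widest range of medians between runs of spots.

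Longer genes had higher ratios (rank correlation 0.37 in the duplicate-spot analysis). If the deposited ratios are unturned, as taken here, a channel or dye effect would turn with the channel order. The correlation was instead above 0 on each turned array, from 0.21 to 0.38. Had the ratios been deposited as treated over untreated, a channel effect would also keep its sign after turning. The test therefore cannot exclude a channel effect in that case. The place of spots would lose the trend once runs of 400 spots are centred, and the correlation was then 0.40. A difference in RNA integrity or labelling between treated and untreated samples may give the trend and cannot be told apart from a real shift toward longer transcripts, since every array holds the same 2 kinds of RNA.

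Ribosomal protein genes stood lower. Those spanning up to 450 bp (19 genes) had a median of -0.71 in the duplicate-spot analysis, against -0.48 for 51 other genes up to 300 bp. Of 10000 random lists of these other genes, a share of 0.0035 lay as low. These values argue against the trend with length alone. The draws treat genes as independent, though, while the estimated correlation within the ribosomal protein list was 0.056, so the share may be too small. A full pull of bright spots toward a deposited ratio of 1 would need -0.43, -0.25, -0.30 and 0.64 on arrays 1 to 4, where the list lay at -0.50, -0.49, -0.49 and -0.49. No single array carries the list's call, whose highest adjusted p without any one array was 1.44e-17 with the preset correlation (camera). With all arrays and an estimated correlation the list did not pass (adjusted p = 0.43, camera). Only array 4 goes against the sign of the pull, and the rule for this test asked for more than 1 such array. The list's medians hardly varied between arrays (SD 0.0038), where a full pull needed -0.43 to 0.64. This argues against a full pull as the only source. A partial brightness effect stays open, as do fewer ribosomal protein transcripts under Congo red.

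For the duplicate-spot analysis 1 of the 8 sign patterns of the 4 arrays, the real one, gave 472 calls, and the highest of the others gave 0. For the planned analysis all 8 patterns gave 0 calls. With 8 patterns a share under 0.05 cannot be reached, and the real pattern was itself chosen, by the orientation rule, from the agreement of the arrays. Unadjusted p under 0.05 was found for 1234 genes with the real signs and at most 184 with other signs in the planned analysis.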

How the results depend on the processing

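The duplicate-spot analysis and its alternatives, the kept placeholder, the runs of 400 spots and the length trend were chosen after the data were seen; the others were planned. The cause of a change was not tested unless given. The planned analysis called 0 genes under 14 alternatives, among them scaling, at least 2 or 3 arrays, single probes, the channel-order term, both pairings averaged, robust variances, and without each array in turn. It called 93 (48 higher, 45 lower) with values as deposited, 4 with quantile normalization, 689 (322, 367) without genes ranging over 2 log2 units, a filter that acts on the tested spread and gave up to 5 false calls in null draws, 437 with arrays 1 and 2, and 3 and 4, as random blocks (consensus correlation -0.23), 537 at an adjusted p under 0.1, 385 (238, 147) by the 2-fold rule without a test, 472 with agreeing spots, 214 (54, 160) with runs of spots centred and 33 (11, 22) with the length trend removed. The 472 calls became 59 as deposited (53 shared), 219 without the length trend (188 shared), 0 unturned, 835 with arrays 1 and 4, and 2 and 3, averaged, and from 0 to 336 without each array; 7 other alternatives stayed within 1.5 times, such as 465 with spots within 0.5 log2 units. With runs of spots centred and the length trend removed 386 passed, but only 233 were shared, and the balance was 205 higher and 181 lower against 149 and 323.

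The count of 4 lists became 0 with an estimated correlation, 1 with fry, 2 with agreeing spots, 2 without the length trend and 1 with both. The ribosomal protein list kept its side of the threshold under all but the estimated correlation (median -0.50, adjusted p = 0.43), with medians from -0.50 to -0.30. Mitochondrial respiration turned to 0.039 with agreeing spots and no length trend. Channel order gave 1 call with agreeing spots. The mean correlation between arrays was 0.45 by Spearman and 0.48 with agreeing spots. SLT2 stayed within its SD of 1.41, which array 1 widens, but went from -0.62 to -1.32 without that array.

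Left unturned, arrays 2 and 4 reversed 52 of the named genes, none past the threshold: LRG1 -0.040, PMA2 -0.084, YVC1 -0.048, MED1 -0.051, AAD3 -0.032, HOF1 0.16, GAT3 0.43, CBK1 0.19, YIR042C 0.018, ECM7 0.12, SEC12 0.044, ERR3 -0.38, ERR2 -0.83, PIR3 -0.34, PRO1 -0.41, MSR1 0.77, TOM6 0.013, ROF1 0.13, TRX1 0.043, TEP1 0.062, DFG5 0.17, CIS3 0.22, HSP150 -0.11, GNA1 0.17, QRI1 -0.052, CCW12 0.013, PKH1 0.14, ZEO1 0.16, STE3 0.14, SPS100 0.75, SPS4 0.23, RED1 0.12, SPR28 0.20, RPL14A 0.20, RPS22A 0.23, RPS31 0.16, ATP15 0.012, COX13 0.14, HSF1 -0.12, HSP10 0.066, SSC1 0.075, SBA1 0.24, HYR1 0.072, TSA1 0.070, CTA1 -0.21, SRX1 0.26, AHP1 0.075, HHF2 0.12, HHF1 0.15, HHT1 0.17, HTA1 0.23, MET17 -0.12. With runs of spots centred SBA1 went to 0.072 and LEU2 to -0.051 (the same with agreeing spots), and to 0.28 and -0.0050 with the length trend also removed; ZEO1 went to 0.0096 with agreeing spots and no length trend. Each ratio already pairs treated with untreated RNA on an array. Signal over background was not analysed here.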

Other observations

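The genes and lists in the first 2 paragraphs were described after their values were seen, and single genes named there beyond the rule were chosen for their values. The test of paired ribosomal protein genes was set down before its result was seen.

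Outside the groups described so far, amino acid genes of the Gcn4 regulon held 3 that rose in the duplicate-spot analysis, SER3 (0.67 ± 0.29), ASN1 (0.55 ± 0.11) and HIS7 (0.61 ± 0.26), and 1 that fell, GLN1, of 42 measured, while the list of 47 in the planned analysis had a median of -0.07 (adjusted p = 0.89, camera). CIT2, the peroxisomal citrate synthase, rose to 1.03 ± 0.53 and was the single call among 13 genes of the tricarboxylic acid and glyoxylate cycles, whose list of 16 had a median of 0.17 (adjusted p = 0.73). In the phosphate regulon PHO81 and GPP2 (0.49 ± 0.18) rose and VTC1 (-0.64 ± 0.15), a subunit of the polyphosphate polymerase, fell (list median 0.07, adjusted p = 0.89). PDC5, a pyruvate decarboxylase, rose to 0.55 ± 0.20 and FBA1, aldolase, fell to -0.53 ± 0.18, as did PDC1. The glycolysis list of 17 had a median of -0.27 (adjusted p = 0.16). It passed without array 4 (adjusted p = 0.037), a test with the preset correlation, while with all arrays an estimated correlation, 0.54 between these genes, gave 0.94 and fry 0.45. Of 15 cell separation and M/G1 genes PIR3 rose and MCM3 (-0.88 ± 0.22), a replicative helicase subunit, and PRY3 (-0.92 ± 0.32) fell (list of 20: median 0.16, adjusted p = 0.46). The 15 G2/M genes had a median of 0.37 (adjusted p = 0.073), with 5 higher and none lower on 4 of 4 arrays, among them CDC20 (1.29 ± 0.86), BUD3 (0.71 ± 0.28) and CLB2 (0.55 ± 0.14). That list passed with genes measured on at least 3 arrays (adjusted p = 0.045) and with runs of 400 spots centred (adjusted p = 0.017), but not with an estimated correlation (adjusted p = 0.75), without the length trend (median 0.23, adjusted p = 0.30) or in the duplicate-spot analysis (7 genes, median 0.12, adjusted p = 0.54, none called).

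The remaining lists did not pass in the planned analysis. Their adjusted p values were 0.46 for ribosome biogenesis (median 0.12), 0.49 for the proteasome (-0.11), 0.87 for the calcineurin response (-0.04) and for NAD, thiamine and vitamin B6 genes (0.21), and 0.89 for drug resistance (0.01), G1/S genes (-0.05), ergosterol synthesis (-0.08), hexose transport (-0.09), the unfolded protein response (-0.02), methionine and sulphate genes (-0.04), the osmotic response (0.01) and iron uptake (0.07).

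Copies of a gene with near-identical sequence did not always read alike. ERR1 stood at -0.90 ± 0.09 while its copies ERR2 and ERR3 stood at 1.32 and 1.41, and THI12 stood at -2.25 ± 0.81 while THI11 and THI5 stood at 2.05 ± 1.34 and 0.86 ± 0.20. CCW22 (-0.98 ± 0.07) and CCW12 (-0.97) read alike. Each of these genes had the same sign on 4 of 4 arrays. ERR1, THI11 and THI12 did not meet the spot filter of the duplicate-spot analysis. ERR2, ERR3, THI5, CCW12 and CCW22 did. That leaves ERR2 with ERR3 and CCW12 with CCW22 to compare, and each pair had the same sign in the planned analysis too. Whether the filter removes such differences between copies can therefore not be judged. Ribosomal protein genes gave a wider test of the hypothesis that spots of 2 copies read the same RNA or RNAs that move together. Over 54 pairs of copies the median absolute difference was 0.22 log2 units against 0.28 in random pairings of the same genes, and 0.0488 of 10000 random pairings were as low. This suggests a weak likeness of the copies, close to the limit set beforehand, and it cannot separate shared hybridisation from shared regulation.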
